A study of Sorghum bicolor with 177 samples.

How the data were processed

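The series holds poly-A selected, directional, paired-end RNA-seq of roots and young leaves of Sorghum bicolor BTx623, the sorghum reference line, grown in hydroponics. The labels list 177 libraries (94 root, 83 leaf) from 80 plants. The deposited table is 1 column per tissue, time and treatment, 57 in all (31 root, 26 leaf), and holds the authors' mean TPM (length-scaled transcript abundance). Quantification used DRAGEN per the submitters' processing notes; its version, the genome build and the gene annotation version are not given in the sources used here. The deposited table has 34924 rows for 34129 genes, since 429 genes stand in several identical rows; the 795 repeats were dropped. As deposited, the columns sum to between 1009075 and 1022382 TPM, and over unique genes each sums to 1000000. Every deposited sum thus exceeds 1000000 because of the repeated rows. The 8 deposited columns summing highest (1020174.5 to 1022382) were recorded as signal, although the authors' values in them are the same mean TPM. All 57 columns were handled as mean TPM.

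TPM keeps no read depth, so the depth behind each value is unknown and no counting interval is given. From 18606 to 20758 genes reached 1 TPM in the root columns and from 15533 to 17977 in the leaf columns. The number of libraries in each mean was read from whether its values are whole multiples of a thousandth of a TPM divided by that number, within 0.001 thousandths: 51 means rest on 3 libraries, 2 (both at 0 h) on 6, 1 on 5, 1 on 4 and 2 on 2. This differs from the labels for 3 root means: zinc excess at 2 d and iron excess at 7 d (2 libraries in the labels, 3 in the mean) and zinc excess at 7 d (5 in the labels, 4 in the mean). All values are printed as the authors' means, without an SD or n of their own.

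Each comparison is a treatment against the control of the same tissue. Mean TPM was taken as log2(mean TPM + 1), so fold changes of genes at low TPM are understated. Genes needed a mean TPM of at least 1 over the columns of the tissue (20481 genes in root, 17088 in leaf). The columns after 0 h were fitted with limma 3.58.1 (R 4.3.3; trend on), with time and treatment as additive terms, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The replicate is the sampling time (6 in root, 5 in leaf), so the p-values measure the spread between times and not between plants. Plants at different times are different plants, apart from 17 root and 3 leaf plants sampled at 2 times, 15 of them roots sampled at both 1 h and 21 d. Errors after ± are standard errors of the fitted log2 difference. A second fit split the treatment effect into early (up to 4 d) and late (7, 14 and 21 d) parts and tested late minus early. Root and leaf were compared in the root minus leaf log2 difference of each group over the 5 shared times (15528 genes). Single times have no test, and genes at least 2-fold apart with the higher mean at 5 TPM or more were counted.

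A total of 31 gene lists, fixed before the data were examined like the design, the named-gene rule and most alternatives, were tested with camera (preset correlation 0.01, and an estimated correlation) and fry from limma, adjusted over the lists of a comparison. fry asks whether the genes of a list moved, on balance, one way, and does not compare them with other genes. The deposited annotation describes 26873 of the genes; symbols with "-like" are those of the closest Arabidopsis gene it gives, and copies of a family named after the same Arabidopsis gene can share reads. Named genes are the 10 largest rises and 10 largest falls past the threshold with the same sign at every time but at most 1 and at least 5 TPM in the higher group. Added to these are up to 4 called members of each list and all called members of the lists of iron regulation, ferritin, ZIP, YSL and OPT transport, metal chelation and phytosiderophore synthesis. At most 2 undescribed genes each way are named by identifier; where no gene passed, the 10 largest differences with 1 sign at every time were eligible as values. Other genes named were chosen after their values were seen.

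The fit was tested on simulated data with 100 genes changed by each size. In root, 74 percent of changes of 1 log2 unit and 99 percent of changes of 2 were recovered; in leaf, 62 and 95 percent. For late minus early, 4 and 68 percent were recovered in root and 2 and 50 percent in leaf. False calls made up 2.7 to 7.14 percent of the calls. The simulation gave every column of a gene the same spread and a constant effect. The real root columns lay at median distances of 0.16 to 0.536 from their average, so these rates need not hold for the data. Alternatives varied the pseudocount, the filter, the scaling, the columns in the fit, the times, the early and late boundary, the trend and the control. Treatments share control columns, so correlations between them were set beside 20 simulations of unchanged groups against the same controls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots. Per-library values were not used here, so no spread between plants is given. A RefSeq gene table was not used here because its locus tags could not be paired with the identifiers of the deposited table.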

Results

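Sorghum plants received 1 of 5 nutrient solutions. The control contained 1 µM ZnSO4 and 50 µM NaFeEDTA, zinc limitation and zinc excess contained 0 and 100 µM ZnSO4, and iron limitation and iron excess contained 0 µM and 1 mM NaFeEDTA. Roots were sampled at 0 h, 1 h, 2 d, 4 d, 7 d, 14 d and 21 d, and discs of a young leaf of the same plants at all of these times but 1 h. The design asks which transcripts each stress moves in each tissue, and when. The 10 most abundant genes took 7.17 to 20.27 percent of the leaf TPM. In root they took 4.27 to 7.74 percent, except under iron excess at 7 d, where 8 genes stood at very high TPM and the share was 35.51 percent.

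Iron limitation in the leaf lowered ferritin transcripts and raised those of some metal transporters. Ferritin, the iron storage protein of plastids, fell in both FER4-like copies, by 3.71 ± 0.95 log2 units for Sobic.008G004800 (adjusted p = 0.0306) and by 3.36 ± 0.92 for Sobic.005G004500 (adjusted p = 0.036), each lower than the control at 5 of 5 times. The ZIP10-like metal transporter Sobic.001G156800 rose by 5.17 ± 1.51, the NRAMP6-like transporter Sobic.002G095600 by 5.23 ± 1.21 and OPT3-like Sobic.001G087700, related to a phloem iron transporter, by 2.94 ± 0.88, each at 4 of 5 times. The largest rise belonged to an asparagine synthetase, Sobic.001G406800 (6.27 ± 1.00, adjusted p = 0.0158, 5 of 5 times), an enzyme that stores nitrogen in asparagine. In total 1161 genes were higher and 320 lower of 17088 (limma, Benjamini-Hochberg).

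Most of this difference was late. At 7, 14 and 21 d the asparagine synthetase stood at 1052, 976.6 and 486.1 TPM against 0.544, 0.1233 and 0.4163 in the control, and ferritin Sobic.008G004800 at 4.59, 4.319 and 1.804 TPM against 141.6, 183.2 and 332 TPM. The late effect differed from the early one for 602 genes (509 in the direction of a higher late effect, 93 of a lower one), among them the asparagine synthetase Sobic.001G406800 (7.32 ± 1.01 log2 units). That count was 31 with the boundary between 7 d and 14 d and 401 after rescaling. At 2 d and 4 d, 483 and 366 genes were at least 2-fold from the control, against 4124, 4120 and 2511 at 7, 14 and 21 d.

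**Figure D1:**
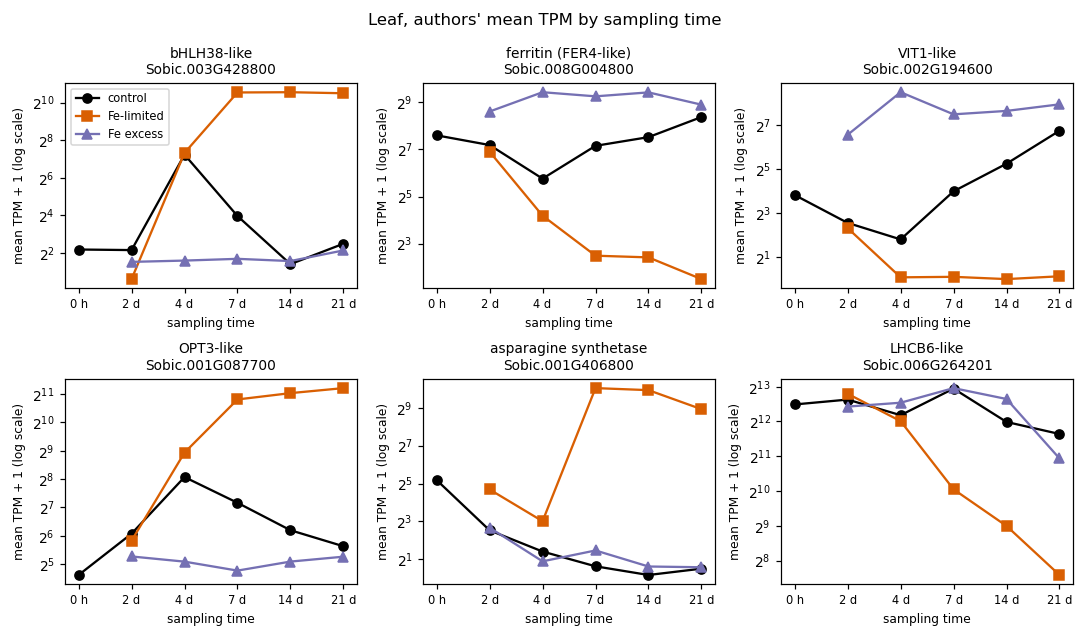
Authors' mean TPM plus 1 (log axis) of 6 leaf genes at each sampling time (0 h to 21 d) in the control, iron limitation and iron excess; each point is 1 mean column without an error. Under iron limitation the bHLH38-like gene stood at 1489 TPM at 7 d against 14.69 in the control, and the LHCB6-like gene at 190.8 TPM at 21 d against 3191.

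Among the 11 iron regulators tested, 0 were higher and 4 lower over all genes (limma; 3 and 4 adjusted over the list alone; 5757 of all genes were at an unadjusted p under 0.05). The 4 were PYE-like Sobic.005G177800 (−2.38 ± 0.59) and Sobic.002G385300 (−1.58 ± 0.44), and ILR3-like Sobic.009G160000 (−2.84 ± 0.66) and Sobic.004G012100 (−0.74 ± 0.18), relatives of bHLH factors that act in the iron deficiency response. The bHLH38-like gene Sobic.003G428800, of the group that rises under iron deficiency in other plants, missed the threshold (4.45 ± 1.74, adjusted p = 0.0895). It read 1489, 1503 and 1446 TPM at 7, 14 and 21 d, against 14.69, 1.661 and 4.643 in the control. BTS-like Sobic.003G262200, an iron-sensing ubiquitin ligase in Arabidopsis, lay at 2.41 ± 0.76 (adjusted p = 0.0513), and VIT1-like Sobic.002G194600, a vacuolar iron importer, at −3.55 ± 1.15 (adjusted p = 0.0553). The remaining PYE-like gene, Sobic.001G355600, lay on the higher side (2.68 ± 1.22, adjusted p = 0.1317), as did BTS-like Sobic.009G222200 (2.53 ± 0.92, adjusted p = 0.0742). Their late effects were 4.66 and 4.06, against early effects of −0.27 and 0.23. For the bHLH38-like gene the late effect was 7.9 and the early one −0.73. The 4 genes called lower had late effects from −1.11 to −4.4. Of the 4 genes of the ferritin list, 1 was higher and 2 lower (2 and 2 adjusted over the list alone). The higher one was TSO2-like Sobic.010G106300 (1.73 ± 0.42), a ribonucleotide reductase subunit and not a ferritin.

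Transport genes went both ways. Of 18 genes of iron efflux and storage, 4 were higher and 0 lower (7 and 2 adjusted over the list alone). These were the ZIP10-like and NRAMP6-like genes above, NRAMP2-like Sobic.001G462500 (2.11 ± 0.64), and an EIN2-like gene, Sobic.001G125500 (1.03 ± 0.23), whose relative acts in ethylene signalling. Of 25 zinc efflux and storage genes, 5 were higher and 0 lower (9 and 1 adjusted over the list alone), among them ZIFL1-like Sobic.008G015800 (1.85 ± 0.39) and HMA2-like Sobic.010G250900 (0.94 ± 0.20), a zinc pump. HMA5-like Sobic.004G079900 (0.79 ± 0.20), a member of that list, is related to copper pumps. In the ZIP list of 12 genes, 1 was higher and 1 lower (2 and 1 adjusted over the list alone), the lower being ZIP1-like Sobic.002G083200 (−1.39 ± 0.38). NAS4-like Sobic.001G151400, a nicotianamine synthase, fell by 0.94 ± 0.23. In the list of YSL and OPT transporters, 3 of 25 were higher and 1 lower, the same counts as when adjusted over the list alone. The ZIP median was −0.07 and its mean 0.24.

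Photosystem and light-harvesting genes were called lower more often than higher. Of 49 photosystem genes 0 were higher and 9 lower (3 and 23 adjusted over the list alone), with PSAF-like Sobic.001G070500 at −1.59 ± 0.40 and PSAN-like Sobic.008G063500 at −1.33 ± 0.35. Of 21 light-harvesting genes 1 was higher and 4 lower (3 and 8 adjusted over the list alone). LHCB6-like Sobic.006G264201 fell by 1.99 ± 0.52 and LHCB1.5-like Sobic.003G209800 by 2.10 ± 0.58, while ELIP1-like Sobic.002G052000, an early light-induced protein made under light stress, rose by 2.74 ± 0.75. Of 10 tetrapyrrole genes 1 was higher and 3 lower (1 and 5 adjusted over the list alone), led by HEMA1-like Sobic.001G202600 (−3.73 ± 1.12), the enzyme that commits glutamate to chlorophyll and haem. With camera the adjusted p was 5.32e-15, 8.69e-07 and 0.000148 for these lists in that order, and the adjusted p = 0.288, 0.336 and 0.336 with an estimated correlation, as none of the 8 lists called kept its call. The other 5 lists called lower with camera were nitrate transport and assimilation, phosphate, class III peroxidases, jasmonate and histones. Their adjusted p = 0.288, 0.336, 0.336, 0.575 and 0.577 with an estimated correlation. By fry 0 of the 30 lists were called in 1 direction, and 19 when genes could move either way.

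Antioxidant enzymes divided by gene. Of 19 genes of superoxide dismutase, catalase and ascorbate peroxidase, 5 were higher and 2 lower (7 and 2 adjusted over the list alone). The haem enzymes CAT1-like Sobic.004G011566 and APX1-like Sobic.001G410200 fell, by 3.63 ± 0.86 and 1.57 ± 0.47, and CSD2-like Sobic.007G166600, a copper and zinc superoxide dismutase, rose by 1.77 ± 0.49. FSD3-like Sobic.010G033000, an iron superoxide dismutase by name, also rose (1.11 ± 0.28). Of 17 nitrate genes 2 were higher and 3 lower over all genes and over the list alone. NRT1.1-like Sobic.001G302800, a nitrate transporter, fell by 3.07 ± 0.65. Among 123 heat shock genes 9 were higher and 2 lower (18 and 2 adjusted over the list alone), and among 356 ribosomal genes 20 were higher and 1 lower (18 and 0), although the ribosomal median of 0.08 lay below the median of all genes and camera put that list on the lower side without a call. Camera also gave the lower side to the iron regulators, whose median was 0.21 and mean 0.49.

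In these leaves the median of all genes was 0.24 log2 units above the control, and the share of the 10 most abundant genes was 14.12, 9.98 and 8.42 percent at 7, 14 and 21 d against 20.27, 16.33 and 12.18 percent in the control. With columns rescaled to a median log ratio of 0 the median was 0.006 and the split became 604 higher and 698 lower, so that 46.4 percent of calls were higher instead of 78.4 percent; 887 of the 1481 calls remained. Then the photosystem list held 0 higher and 7 lower, the ribosomal list 4 higher and 9 lower, and the heat shock list 3 and 3. The rises of ZIP10-like Sobic.001G156800, OPT3-like Sobic.001G087700, NRAMP2-like Sobic.001G462500 and CSD2-like Sobic.007G166600 and the fall of HEMA1-like Sobic.001G202600 then missed the threshold, with adjusted p from 0.0513 to 0.0629, at values close to those above (4.94, 2.70, 1.87, 1.54 and −3.97). The count rested on the late times: it was 1 higher and 1 lower without 7 d, 0 and 0 without 14 d or without 21 d, 2118 higher without 4 d, and 3942 and 675 with the late times alone. It was 3 and 6 with only the iron-limited and control columns, and 4 and 3 without the filter on mean TPM.

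Iron limitation in the root gave 0 genes past the threshold in either direction (limma; 100 genes at an unadjusted p under 0.05) and 0 for late minus early (1878 unadjusted). The largest difference with 1 sign at 6 of 6 times among described genes was that of a ribosomal protein S12, Sobic.004G303433 (1.42 ± 0.33, adjusted p = 1.00). NYC1-like Sobic.003G010600, a chlorophyll b reductase, lay at −0.94 ± 0.31 and the wound-induced Sobic.006G231200 at −0.82 ± 0.25. Adjusted over the list alone, 0 ferritin genes were higher and 2 lower of 4, with FER4-like Sobic.008G004800 at −0.85 ± 0.30 and Sobic.005G004500 at −0.52 ± 0.19. Over the late times the bHLH38-like gene Sobic.003G428800 lay at 1.16 ± 0.38 and PYE-like Sobic.001G355600 at 1.36 ± 0.34, and 4 of 12 iron regulators were higher adjusted over the list alone with those times by themselves. Histone and ribosomal lists were called higher with camera (adjusted p = 2.58e-12 and 0.00311), which became adjusted p = 0.835 and 0.945 with an estimated correlation. Beside them, the root controls at 2 d and 4 d had histone medians of −1.42 and −1.01 log2 units relative to the average root column, and iron limitation at 2 d −0.48.

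The direct test of the root against the leaf effect of iron limitation passed for 5 of 15528 genes. The asparagine synthetase Sobic.001G406800 (root minus leaf −6.10 ± 1.05, adjusted p = 0.047) was at 0.21 ± 0.39 in root, and the cytochrome P450 CYP78A9-like Sobic.002G272700 (4.63 ± 0.82, adjusted p = 0.047) was at 0.08 ± 0.41 in root and −4.22 ± 0.64 in leaf. MYB86-like Sobic.002G388700, the galactosyltransferase Sobic.002G068800 and the kinase Sobic.009G079100 rose in the leaf by 3.34 ± 0.57, 3.65 ± 0.70 and 3.37 ± 0.62, and were named after their values were seen. The count was 206 without 2 d, 293 without 4 d and 0 without 7 d, 14 d or 21 d, and 17 with a pseudocount of 0.1 and 9 after rescaling.

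Iron excess in the leaf gave 0 genes past the threshold (limma; 521 genes at an unadjusted p under 0.05) and 0 for late minus early (196 unadjusted). This fit takes its spread from the columns of all treatments, iron limitation included. With only the iron-excess and control columns (limma), 0 genes passed as well, but 1738 were at an unadjusted p under 0.05. The lowest adjusted p was then 0.408, against 0.9993 in the main fit. The 0 calls therefore do not show that no gene responded. Transcripts of VIT1-like Sobic.002G194600 and of both FER4-like genes read above the control at 5 of 5 times. VIT1-like Sobic.002G194600 read 94.17, 363.5, 180.3, 201 and 247.5 TPM at 2, 4, 7, 14 and 21 d against 4.894, 2.5, 14.97, 37.19 and 107 (3.57 ± 1.15, adjusted p = 0.9993). FER4-like Sobic.008G004800 lay at 1.93 ± 0.95 and Sobic.005G004500 at 1.68 ± 0.92, while the other VIT1-like gene, Sobic.006G109000, lay at −0.02 ± 0.20. Of 18 genes of iron efflux and storage 2 were higher and 0 lower adjusted over the list alone; Sobic.006G161800 of that list, from the vacuolar iron transporter family, lay at 1.67 ± 0.43. On the lower side were a chitinase, Sobic.K029900 (−2.09 ± 0.67), and the undescribed Sobic.001G098600 (−2.41 ± 0.59). Camera called 7 lists lower, among them ribosomal (adjusted p = 3.16e-10) and photosystem genes (2.85e-06), and each had an adjusted p = 0.848 with an estimated correlation.

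In the root, iron excess gave 0 genes past the threshold (limma; 1537 at an unadjusted p under 0.05). VIT1-like Sobic.002G194600 lay at 1.82 ± 0.45 (adjusted p = 0.653) at 6 of 6 times, the aquaporin NIP1;2-like Sobic.004G102200 at 1.93 ± 0.62, and ORG1-like Sobic.003G241900, named after a gene that responds to OBP3, at −1.60 ± 0.50. Of 3 genes of phytosiderophore synthesis, which makes the iron chelators of grasses, 0 were higher and 2 lower adjusted over the list alone. NAS4-like Sobic.001G395900 lay at −2.21 ± 0.78 and Sobic.001G443100 at −1.002 ± 0.43. Of 19 genes of iron efflux and storage, 3 were higher and 1 lower adjusted over the list alone. Camera called 12 of 31 lists, among them ribosomal (adjusted p = 2.41e-13), histone (1.04e-07) and class III peroxidase genes (1.15e-09), all higher, and 0 with an estimated correlation (adjusted p = 0.581 for these 3). Beside these lists, the control roots at 2 d and 4 d had ribosomal medians of −0.65 and −0.63 and peroxidase medians of −1.19 and −0.75 against the average root column.

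The late effect of iron excess in root was lower than the early one for 81 genes and higher for 0 (limma). The median of all genes was −0.17 over the late times and 0.047 over the early ones. That count fell to 0 once the 7 d mean was rebuilt without the 8 dominant genes, after rescaling, with a pseudocount of 0.1 and with the boundary between 7 d and 14 d. With 7 d left out, 1 gene was higher under iron excess in root. Root and leaf effects of iron excess differed for 0 genes (limma; 1124 unadjusted).

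Zinc limitation in the root raised 2 genes and lowered 0 of 20481 (limma; 1298 at an unadjusted p under 0.05). ZIP1-like Sobic.002G083200, of the zinc and iron transporter family, rose by 1.98 ± 0.34 (adjusted p = 0.0478, 6 of 6 times) and reached 21.4, 76.4 and 137.6 TPM at 7, 14 and 21 d against 5.322, 11.73 and 20.84 in the control. RNS3-like Sobic.002G385500, a T2 ribonuclease, rose by 1.39 ± 0.21 (adjusted p = 0.0112, 6 of 6 times). In the ZIP list 1 of 17 genes was higher and 0 lower over all genes, and 7 were higher and 0 lower adjusted over the list alone. Examples are ZIP1-like Sobic.007G075700 (2.95 ± 0.60, adjusted p = 0.0975 over all genes), ZIP4-like Sobic.010G171300 (2.24 ± 0.45) and ZIP5-like Sobic.007G064900 (2.15 ± 0.65). Camera called the list higher (adjusted p = 2.58e-08; adjusted p = 0.0947 with an estimated correlation) and fry gave an adjusted p of 0.0277, the lowest of 31 lists.

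**Figure D2:**
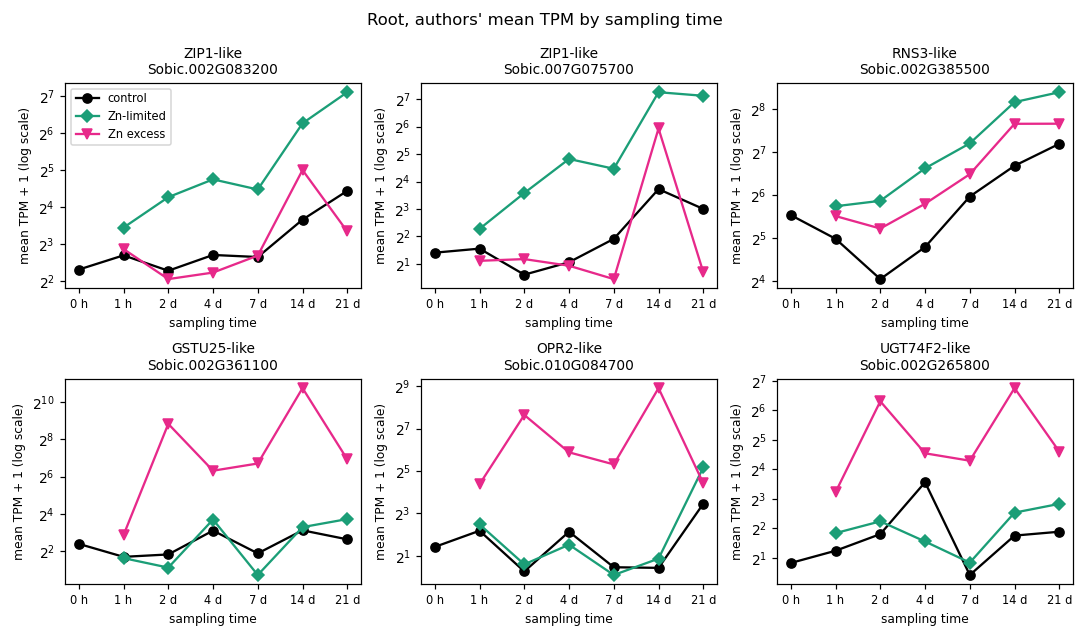
Authors' mean TPM plus 1 (log axis) of 6 root genes at each sampling time in the control, zinc limitation and zinc excess; each point is 1 mean column without an error. ZIP1-like Sobic.007G075700 stood at 151.7 TPM under zinc limitation at 14 d against 12.2 in the control, and GSTU25-like Sobic.002G361100 at 1704 TPM under zinc excess against 7.676.

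Camera also called 6 other root lists under zinc limitation, and 0 of the 7 in all with an estimated correlation. Photosystem genes were lower (26 genes, median −0.41) and class III peroxidases higher (110 genes, median 0.27), with adjusted p = 0.843 and 0.966 with an estimated correlation. Beside these lists, the controls at 2 d and 4 d had peroxidase medians of −1.19 and −0.75 against the average root column, and medians of 0.294 and 0.382 for the 50 genes with the highest leaf to root ratio, against −0.351 and −0.22 under zinc limitation. Late minus early gave 0 genes (2014 unadjusted). Of the 2 calls, 0 were left without 2 d, 4 d, 7 d or 14 d and 1 without 21 d, while leaving out 1 h gave 12 higher and 1 lower. Other fits gave 0 with the late times alone, with only the zinc-limited and control columns and without both 2 d and 4 d, 1 after rescaling, without the trend, without the filter or with the iron-excess mean rebuilt, and 4 without the means of 2 plants. With 1 h and 21 d averaged, which are the same plants, 9 were higher and 4 lower. In each fit with 1 gene left, RNS3-like Sobic.002G385500 kept its call and ZIP1-like Sobic.002G083200 lost it at about the same value (1.98, adjusted p = 0.0713 after rescaling).

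Zinc limitation in the leaf gave 0 genes past the threshold (limma; 192 at an unadjusted p under 0.05), and 0 for late minus early (123 unadjusted). CCH-like Sobic.004G164200, related to a copper chaperone, lay at 1.91 ± 0.68 and read a mean over times of 1018 TPM against 272.6. The flowering regulator FT-like Sobic.009G199900 lay at −1.54 ± 0.48, and chalcone synthase Sobic.005G136200, at the entry to flavonoids, at 1.24 ± 0.42 (adjusted p = 1.00 for each, 5 of 5 times). Of 12 ZIP genes 0 were called either way; ZIP4-like Sobic.010G171300 lay at 1.03 ± 0.46 and ZIP1-like Sobic.007G075700 at 0.94 ± 0.43. Photosystem genes were called lower with camera (median −0.16, adjusted p = 6.25e-12; adjusted p = 0.812 with an estimated correlation), as were 3 further lists, and the methionine cycle higher; 0 of the 5 lists held with an estimated correlation. Root and leaf effects of zinc limitation differed for 0 genes (limma; 360 unadjusted).

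Zinc excess in the root raised 248 genes and lowered 36 (limma). GSTU25-like Sobic.002G361100, a glutathione S-transferase that joins toxic compounds to glutathione, rose by 4.68 ± 0.66 (adjusted p = 0.000533, 6 of 6 times) and reached 1704 TPM at 14 d against 7.676. The cytochrome P450 CYP81D5-like Sobic.001G082400 rose by 4.02 ± 0.54 (adjusted p = 0.000278), the glycosyltransferase UGT74F2-like Sobic.002G265800 by 3.18 ± 0.42 (adjusted p = 0.000278) and the oxophytodienoate reductase OPR2-like Sobic.010G084700 by 4.61 ± 0.74 (adjusted p = 0.0013), each at 6 of 6 times. A gibberellin 20-oxidase, Sobic.001G166401, rose by 3.55 ± 0.54 and the quinone reductase FQR1-like Sobic.002G074400 by 3.24 ± 0.51.

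Of 88 glutathione S-transferases 24 were higher and 0 lower (38 and 2 adjusted over the list alone). Camera gave the list an adjusted p of 2.54e-12 (adjusted p = 0.151 with an estimated correlation) and fry 0.00225. GSTF13-like Sobic.003G164800 rose by 3.71 ± 0.54 and GSTU8-like Sobic.003G426000 by 2.94 ± 0.52. Of 39 jasmonate genes 4 were higher and 0 lower (7 and 1 adjusted over the list alone). All 4 were relatives of Arabidopsis OPR1 and OPR2, which by background reduce several enones and, unlike OPR3, are not the main jasmonate enzymes: OPR2-like Sobic.010G084700 and Sobic.010G084600 (3.22 ± 0.58), and OPR1-like Sobic.010G084400 (2.44 ± 0.40) and Sobic.006G091700 (1.90 ± 0.29). Of 136 heat shock genes 6 were higher and 1 lower (11 and 1 adjusted over the list alone), with the mitochondrial small heat shock protein Sobic.004G228900 at 2.06 ± 0.47.

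Photosystem genes, at low level in root, were lower: 0 higher and 4 lower of 26 (0 and 13 adjusted over the list alone). PSBP-1-like Sobic.002G030200 fell by 1.85 ± 0.44, to a mean of 1.924 TPM against 11.79. Camera gave this list an adjusted p of 1.41e-10 (adjusted p = 0.151 with an estimated correlation) and fry 0.0198. The median of the 50 genes with the highest leaf to root ratio was also lower under zinc excess than in the control at 6 of 6 times, for example −0.457 against 0.294 at 2 d, −0.43 against 0.382 at 4 d and −0.596 against −0.086 at 14 d. These 50 were picked by level in the same data and may include photosystem genes, so they are not independent of the list. CCL-like Sobic.003G107300 fell by 2.49 ± 0.55 and the vacuolar malate transporter TDT-like Sobic.002G245400 by 1.55 ± 0.33. In the ZIP list 0 of 17 were higher and 1 lower (1 and 2 adjusted over the list alone): ZIP10-like Sobic.001G142800 fell by 1.23 ± 0.31, but missed the threshold after rescaling (−1.26, adjusted p = 0.0583) and kept its call in 2 of 17 other fits. ZIFL1-like Sobic.005G024800, of a family that moves zinc and chelators, rose by 1.36 ± 0.25. Of 24 zinc efflux and storage genes 1 was higher and 0 lower over all genes and over the list alone. Of 4 metal chelation genes 0 were called over all genes and 2 were higher adjusted over the list alone, the metallothioneins MT2A-like Sobic.003G071901 (1.29 ± 0.39) and MT2B-like Sobic.005G228700 (0.69 ± 0.25). Camera also called the lists of aquaporins (32 genes), the methionine cycle (9 genes) and abscisic acid and LEA proteins (66 genes) higher, each with an adjusted p = 0.844 with an estimated correlation.

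These counts rested on the early columns as well as the late ones. The controls at 2 d and 4 d gave 5289 and 2576 genes at least 2-fold from zinc excess. At 21 d there were 3129, of which 1241 were higher and 1888 lower, and at 1 h, 7 d and 14 d there were 344, 804 and 1098. Without both times 18 genes were higher and 0 lower, among them GSTU25-like Sobic.002G361100 and UGT74F2-like Sobic.002G265800, and the glutathione S-transferases held 1 higher and 0 lower (28 and 1 adjusted over the list alone). The 4 root markers of the Casparian strip, the endodermal barrier, were then all lower adjusted over the list alone (median −0.67). Leaving out 1 time gave 84 higher and 9 lower (2 d), 129 and 0 (4 d), 146 and 11 (7 d), 92 and 8 (14 d) or 364 and 60 (1 h), and averaging 1 h and 21 d, which are the same plants, gave 356 and 79. The late times alone gave 110 and 4, a filter at 5 TPM 150 and 21, and only the zinc-excess and control columns 0 and 0; lower calls were 17 without the means of 2 plants and 20 without the filter.

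Zinc excess in the leaf raised 5 genes and lowered 0 (limma; 2060 at an unadjusted p under 0.05). Sobic.001G190300, annotated as loricrin-like, rose by 3.75 ± 0.22 (adjusted p = 2.13e-09), from a mean of 1.26 to 30.45 TPM. The undescribed Sobic.003G397500 rose by 4.19 ± 0.65 (adjusted p = 0.011), Sobic.009G038401 by 3.20 ± 0.41 (adjusted p = 0.000925) and Sobic.001G233200 by 2.92 ± 0.29 (adjusted p = 2.11e-05). The last of these exceeds the number of undescribed genes allowed by the naming rule and was named after its values were seen. The fifth was a methyltransferase of the jasmonate list, Sobic.003G269700 (1.74 ± 0.30, adjusted p = 0.0393), 1 of 31 genes there over all genes and over the list alone. All 5 were higher at 5 of 5 times.

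The photosystem list was lower under zinc excess in the leaf, with 0 of 49 genes called over all genes or over the list alone, a median of −0.45 and an adjusted p of 7.76e-35 with camera. It was the single list of 30 whose call held with an estimated correlation (adjusted p = 0.0321), while fry, which does not compare it with other genes, gave an adjusted p of 0.276. LHCB6-like Sobic.006G264201 read 1944, 4817, 5882, 5257 and 762.5 TPM at 2, 4, 7, 14 and 21 d against 6337, 4642, 7887, 4057 and 3191, and the bHLH38-like gene Sobic.003G428800 stood at ratios of 112.86, 0.04, 0.81, 0.81 and 56.16 to the control at these times. Light-harvesting (median −0.38) and tetrapyrrole genes (median −0.43) were also called with camera, but had an adjusted p = 0.133 each with an estimated correlation. The median of all genes was 0.21 here and −0.013 after rescaling. The number of genes was 3 without 2 d or without 4 d, 2 with the late times alone, 3 with a filter at 5 TPM and 8 without the filter.

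The direct test of the root against the leaf effect of zinc excess passed for 36 of 15528 genes, 31 with a higher effect in root. CYP81D5-like Sobic.001G082400 differed by 4.65 ± 0.66 (adjusted p = 0.00117; leaf 0.07 ± 0.50) and OPR2-like Sobic.010G084700 by 5.33 ± 0.82 (adjusted p = 0.0032; leaf −0.24 ± 0.49). AOX1A-like Sobic.006G202500, named after its values were seen, differed by 3.68 ± 0.48 (root 2.59 ± 0.40). By its Arabidopsis match it is a mitochondrial alternative oxidase, but its rice description is that of a transposon protein. The loricrin-like Sobic.001G190300 differed by −3.49 ± 0.41, with 0.39 ± 0.31 in root. The count was 5 without 2 d, 14 without 4 d, 19 without 7 d, 23 without 14 d and 70 without 21 d, and 88 after rescaling. Late minus early gave 0 genes in root (limma; 3929 unadjusted) and 0 in leaf (406 unadjusted).

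**Figure D3:**
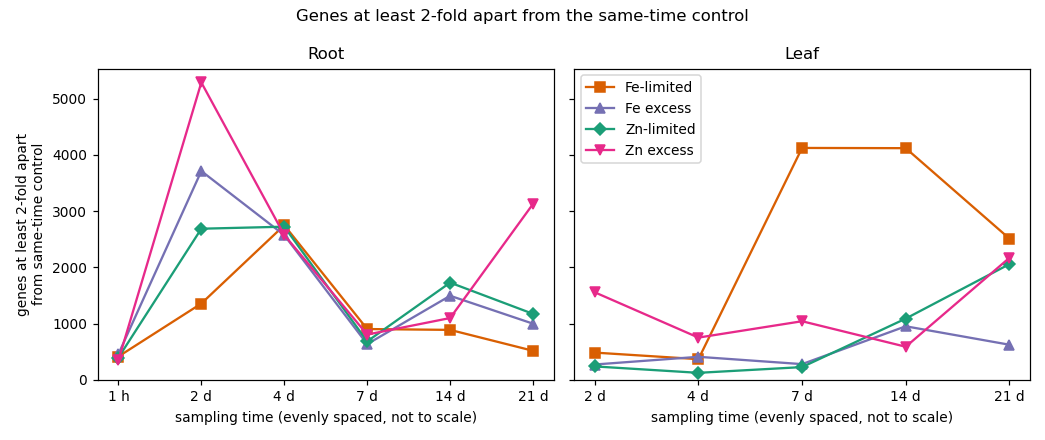
Number of genes at least 2-fold from the same-time control, with the higher mean at 5 TPM or more, at each sampling time in root (1 h to 21 d) and leaf (2 d to 21 d) for the 4 treatments. Leaf iron limitation stood at 4124 genes at 7 d, and root zinc excess at 5289 genes at 2 d. The root counts at 2 d also hold the difference of the control itself. Against the 0 h roots, the 2 d control had 2330 genes higher and 4422 lower, and zinc excess at 2 d had 965 and 970.

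Differences against the control were also compared between treatments, across genes, which are not independent replicates. In root, zinc limitation and zinc excess had r = 0.558 and a covariance of 0.0647, against r = 0.498 and 0.0299 for unchanged groups that share these controls. With the times split, so that each treatment and its controls came from other times, r was 0.349. Iron excess with zinc limitation (r = 0.582, the highest) and with zinc excess (r = 0.53) also lay above the simulated value, and stood at 0.293 and 0.28 with that split. The root controls at 2 d and 4 d that these pairs share lay at median distances of 0.536 and 0.419 from the other columns, while the simulation gave all columns of a gene the same spread. Iron limitation, with 0.512 at 2 d, had r = 0.207 with zinc excess, 0.317 with iron excess and 0.463 with zinc limitation, all below the simulated value. In leaf, all 6 pairs lay below the simulated r of 0.499, from 0.089 (iron limitation and iron excess) to 0.413, and ranged from −0.043 to 0.167 with the times split. By covariance, iron limitation with zinc excess in leaf (0.042) lay above the simulated 0.0356. Shared calls could not be assessed, since 4 of the 8 comparisons had 0 calls (limma) and the pairs left had at most 0.34 shared genes for independent lists.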

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

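The tests of few genes taking most of the total, of dividing cells and of a near-empty library were chosen only after the result was seen. So were the test of the percent of leaf level and the exchange of times that share plants as 1 unit. The other tests of the 3 patterns were set before their own results were seen, but after those patterns had been noticed. The splits of the root times into early and late were set before the data were examined. The late minus early and root minus leaf results below were brought up because a direct test found that an effect differed, and the 3 patterns weighed at the end were noticed in single columns.

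Late and early effects of iron limitation in the leaf differed for 602 genes. Higher late minus early values belonged to the asparagine synthetase Sobic.001G406800 (7.32), ATAF1-like Sobic.009G142200 (6.99), NRAMP6-like Sobic.002G095600 (6.78), PAN-like Sobic.010G110100 (6.14), the FAD oxidoreductase Sobic.002G253500 (6.05) and the histidine biosynthesis gene Sobic.003G119900 (5.93). Smaller rises were those of ELIP1-like Sobic.002G052000 (4.30), a class III peroxidase, Sobic.001G444700 (3.22), the heat shock genes Sobic.003G350700 (2.88) and Sobic.001G454000 (1.70), ZIFL1-like Sobic.008G015800 (2.32), PTR2-like Sobic.001G276400 (2.31), TSO2-like Sobic.010G106300 (2.16), PAP26-like Sobic.010G205200 (2.02) and the methionine cycle gene Sobic.003G108800 (1.00).

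Lower late values under iron limitation belonged to the undescribed Sobic.009G165200 (−5.80), the 2Fe-2S protein Sobic.009G225600 (−5.19), NDA2-like Sobic.003G343500 (−4.57), ILR3-like Sobic.009G160000 (−3.89), NRT1.1-like Sobic.001G302800 (−3.61), LHCB1.5-like Sobic.003G209800 (−3.60), HEMA1-like Sobic.006G234100 (−3.52), LHCB6-like Sobic.006G264201 (−3.31) and APX1-like Sobic.001G410200 (−3.10). Others were the nitrite and sulfite reductase Sobic.009G189400 (−2.48), PSAF-like Sobic.001G070500 (−2.42), PORA-like Sobic.001G206200 (−2.35), PSAN-like Sobic.008G063500 (−2.08), SPX2-like Sobic.004G084900 (−1.71), a histone, Sobic.002G291066 (−1.56), and a glutathione S-transferase, Sobic.001G011600 (−1.03). In root, the late and early effects of iron excess differed for 81 genes in the main fit, all lower late. No gene was left after rescaling, with the iron-excess mean rebuilt, with the smaller pseudocount or with the later boundary. The 81 therefore depend on the processing and do not establish a late effect.

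Root and leaf effects of zinc excess differed for 36 genes, among them the gibberellin 20-oxidase Sobic.001G166401 (root minus leaf 5.44), OPR2-like Sobic.010G084700 (5.33), CYP81D5-like Sobic.001G082400 (4.65), OPR1-like Sobic.006G091700 (2.46) and the loricrin-like Sobic.001G190300 (−3.49). For iron limitation 5 genes differed, among them the asparagine synthetase Sobic.001G406800 (−6.10) and CYP78A9-like Sobic.002G272700 (4.63).

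Treatment and control were exchanged within times to ask what chance alone calls, and times that share plants (1 h and 21 d in root, 2 d and 7 d under zinc excess) were exchanged together. This replaced an exchange of each time alone, planned before, which counted the same plants as independent. The exchange left too few splits to exclude chance in any comparison. In root it was 1 of 16 for zinc limitation (real 2, highest other 0), 1 of 8 for zinc excess (real 284, highest other 0), and 16 of 16 with a real 0 for iron limitation and iron excess (highest other 0 in both). In leaf it was 1 of 16 for iron limitation (real 1481, highest other 0), 1 of 8 for zinc excess (real 5, highest other 1), and 16 of 16 for iron excess (real 0, highest other 1) and zinc limitation (real 0, highest other 0). Splitting the root times otherwise into early and late left too few splits as well. For iron excess it was 1 of 10 (real 81, highest other 0), where 81 is the main-fit count that rescaling did not keep. It was 10 of 10 with a real 0 for iron limitation, zinc limitation (highest other 0 in both) and zinc excess (highest other 1). Root against leaf also had too few: 1 of 8 for zinc excess (real 36, highest other 1), 16 of 16 with a real 0 for iron excess (highest other 0) and zinc limitation (highest other 1), and 3 of 16 for iron limitation (real 5, highest other 219), where the larger count of another split points to a structure of the samples or to an effect confined to some times, which were not told apart by a test.

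The bHLH38-like gene Sobic.003G428800 also stood high in some leaf means outside iron limitation, at 503.3 TPM under zinc excess at 2 d, a ratio of 112.86 to the same-time control on the scale with 1 TPM added. A plant of late iron limitation among the 3 of the mean would carry its part of the late rise into the 50 other genes that rise most, but their median share of it was 0.051 (quartiles 0.013 and 0.111), which excludes it. A few genes taking most of the total was excluded too, since the ratio was still 83.1 after rescaling. A low iron state in some of these plants was not tested.

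The root controls at 2 d and 4 d and iron limitation at 2 d had the lowest class III peroxidase medians of the root columns, −1.188, −0.753 and −1.055 (next −0.47, zinc limitation at 2 d). Their median distances from the other columns were 0.536, 0.419 and 0.512, so that by distance the 4 d control lay below iron excess at 7 d (0.492). A scaling difference was excluded, as rescaling left the distances at 0.507, 0.422 and 0.48 (lowest fall −0.8 percent). Fewer dividing cells stays open: the highest of the 3 histone medians was −0.475, but zinc excess at 21 d reached −1.024 with a peroxidase median of −0.309. Leaf material stays open only as a trace, with 50 leaf genes at a lowest median of 0.294 (quartiles −0.471 and 1.155). This value lay just under the bound of 0.3 set for excluding it, but by less than its spread. A share large enough to lower the peroxidases was excluded, since the leaf genes stood at no more than 0.261 percent of their leaf level.

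Root iron excess at 7 d held 8 genes at very high TPM, for example the ribosomal protein L10 gene Sobic.008G004000 at 74324.5 against 26.76 in the control. Together their excess was 33.42 percent of the column, where 1 near-empty library among 3 would give 33.33. The median log2 ratio of the other well expressed genes to their mean in the other root columns was −0.627, against −0.585 from that explanation. Since TPM sums to a fixed total, an excess of this size lowers the other genes about as much whatever its cause. The ratio is therefore no separate support. The labels list 2 libraries for this mean, while its values are those of 3. A near-empty library therefore fits, but it was thought of after these values were seen and the library itself was not examined. The 8 genes were picked as standing above the other root means, and none exceeded 1535.7 TPM in any of those. This covers iron excess at 4 d and 14 d, and argues against a response of such size lasting over these times. A response of these genes to iron excess confined to 7 d stays open, with median differences of 0.656 at 4 d and 0.23 at 14 d.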

How the results depend on the processing

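The tests without 2 d and 4 d, with the iron-excess mean rebuilt, with 1 h and 21 d averaged, and with rescaling for late minus early and for root minus leaf were chosen only after the result was seen. No paired analysis was possible because treated and control plants differ and the columns are group means without replicate numbers, so the replicate block and the fits without each replicate were not run; root minus leaf does use columns of the same plants. Averaging 1 h and 21 d in root, which are the same plants, gave 9 higher and 4 lower for zinc limitation and 356 and 79 for zinc excess. Root zinc limitation (2 higher) gave 1 without the filter, 1 rescaled, 1 rebuilt, 1 without trend, 0 with only its own and control columns, 0 with late times, 0 without 2 d and 4 d and 4 without means of 2 plants; leave-one-out over times gave 0 to 12, and 0 to 1 lower. Root zinc excess (248 higher, 36 lower) gave 150 and 21 at 5 TPM, 0 and 0 with only its own columns, 110 and 4 with late times, 18 and 0 without 2 d and 4 d, and 84 to 364 and 0 to 60 in leave-one-out fits; lower calls were 20 without the filter and 17 without means of 2 plants. Root iron excess gave 0 to 1 higher in leave-one-out fits. Leaf iron limitation (1161 and 320) gave 4 and 3 without the filter, 604 and 698 rescaled, 3 and 6 with only its own columns, 3942 and 675 with late times, and 0 to 2118 and 0 to 439 in leave-one-out fits. Leaf zinc excess (5) gave 8 without the filter, 3 at 5 TPM, 2 with late times and 3 to 7 in leave-one-out fits.

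Late minus early for root iron excess (81) gave 0 with a pseudocount of 0.1, 0 with the boundary between 7 d and 14 d, 0 rescaled and 0 rebuilt. That boundary gave 2 for root zinc limitation, 1 for leaf iron excess, 1 for leaf zinc limitation and 31 for leaf iron limitation (602), which gave 401 rescaled. Root against leaf gave 17 with a pseudocount of 0.1, 9 rescaled and 0 to 293 in leave-one-out fits for iron limitation (5), and 88 rescaled and 5 to 70 for zinc excess (36). With an estimated correlation the lists called fell to 0 in all comparisons (from 7 in leaf iron excess, 8 leaf iron limitation, 5 leaf zinc limitation, 12 root iron excess, 2 root iron limitation, 5 root zinc excess and 7 root zinc limitation) but leaf zinc excess, with 1 of 7.

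With the times split between the 2 treatments, r in root fell from 0.317 to −0.002 (iron limitation and iron excess), 0.463 to 0.042 (both limitations), 0.207 to −0.125 (iron limitation and zinc excess), 0.582 to 0.293 (iron excess and zinc limitation), 0.53 to 0.28 (both excesses) and 0.558 to 0.349 (both zinc treatments). Treated as well as control columns then differ, so the fall cannot be read as the part due to shared controls. In leaf, in the same order, it went from 0.089 to −0.043, 0.213 to 0.074, 0.269 to 0.167, 0.393 to −0.004, 0.413 to 0.029 and 0.413 to 0.029. Genes at least 2-fold apart, summed over times, went with the 0 h control from 6822 to 19318 (root iron limitation), 9867 to 16566 (root iron excess), 9386 to 15852 (root zinc limitation), 2531 to 10564 (leaf iron excess), 3730 to 11389 (leaf zinc limitation) and 6103 to 14592 (leaf zinc excess); leaf iron excess gave 4016 with a minimum of 1 TPM. Root zinc excess and leaf iron limitation rose by a smaller factor. At 2 d alone, the 0 h control lowered the root counts of both excesses and raised those of both limitations. Zinc excess went from 5289 to 965 higher and 970 lower, and iron excess from 3713 to 1097 and 980. Of the named genes past the threshold, 2 of 5 in leaf zinc excess and 0 of 96 in leaf iron limitation kept it in every fit. In root, 0 of 38 in zinc excess and 0 of 2 in zinc limitation did, and 0 reversed in either tissue. Fits with fewer columns or times have less power by construction; otherwise the cause was not tested.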

Other observations

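The patterns below were chosen only after they were seen and were not themselves tested, so they are hypotheses. Some of their members entered tests above: the bHLH38-like gene under zinc excess at 2 d, and the Casparian strip markers in zinc-excess roots. In leaf, the iron importer VIT1-like Sobic.002G194600 and the ferritin FER4-like Sobic.008G004800 moved opposite to the bHLH38-like regulator Sobic.003G428800 in some means outside the iron treatments, though not in all. Zinc excess at 2 d had the regulator at 503.3 TPM, with VIT1-like at 0.04633 and ferritin at 31.55, while zinc excess at 4 d had 5.503, 342.8 and 979.1 in that order. The same-time controls stood at 3.468, 4.894 and 144.9 TPM at 2 d and at 149.7, 2.5 and 53.18 TPM at 4 d. Zinc limitation at 21 d went against this pattern, with all of them above the control, at 66.5, 539 and 795.8 TPM against 4.643, 107 and 332.

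Control roots lay furthest from the 0 h roots at 2 d and 4 d, with 6752 and 6415 genes at least 2-fold apart. The counts were 2026 at 7 d, 1213 at 14 d and 2302 at 21 d. Most treated roots lay nearer to 0 h at 2 d and 4 d. At 2 d zinc excess had 965 genes higher and 970 lower, iron excess 1097 and 980, and zinc limitation 1447 and 2105. Iron limitation had 2465 and 4291, beside 2330 and 4422 in the control. At 4 d all treatments had fewer than the control, the most being zinc excess with 2072 and 1759 against 2794 and 3621. The Casparian strip markers had a mean of 4.15 TPM in zinc-excess roots at 21 d against 15.22 in the control, and 6.78 and 12.51 TPM in the controls at 2 d and 4 d.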
